A study of Homo sapiens with 9 samples.

How the data were processed

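The labels describe 9 cultures of the human hepatocellular carcinoma line HuH-7, each sequenced as 1 library: an untreated control, acetaminophen (10 mM), exosomes obtained from serum (1 ml), acetaminophen with exosomes, caffeine at 2 mM, acetaminophen with caffeine, arsenic at 5 µM, arsenic at 15 µM, and arsenic at 5 µM with copper at 5 µM. Per the labels, total RNA was isolated with the mirVana kit, ribosomal RNA was removed with RiboMinus, libraries were made with the Ion Total RNA-Seq Kit v2, and sequencing was done on an Ion Torrent Proton. The authors deposited raw read counts per Ensembl gene identifier, 1 file per library, and per the submitters' processing notes reads were aligned with TopHat2 2.0.13 to GRCh37 and counted with HTSeq 0.6.1. The annotation release, the strand setting, the read filters, the exposure times and the source of the serum are not given in the sources used here, so reads in antisense or overlapping genes may be assigned either way.

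Each file holds 63677 gene identifiers and HTSeq summary lines, which took 42.3% (acetaminophen) to 70.3% (acetaminophen with exosomes) of the reads and were left out of library sizes. Gene names came from RefSeq, GENCODE 29 and gene name tables: 39699 identifiers had a symbol and 52526 a GENCODE 29 gene type. GENCODE 29 uses GRCh38 and served for names, types, transcript length, GC content and neighbour order alone; no coordinates were converted. Identifiers without a symbol were tested and are not named, and levels of XIST and Y-linked genes were not examined.

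Counts on genes were 951816 (control), 1271896 (acetaminophen), 3024317 (exosomes), 658725 (acetaminophen with exosomes), 8227906 (caffeine), 5430432 (acetaminophen with caffeine), 3671322 (arsenic 5 µM), 2985304 (arsenic 15 µM) and 2638534 (arsenic 5 µM with copper). In the control a gene at 50 CPM has 52 counts and a 95% counting interval of 37.5 to 65.8 CPM, and one at 5 CPM has 5 counts and 1.57 to 11.3 CPM. In the caffeine library these intervals are 45.3 to 54.9 and 3.64 to 6.78 CPM.

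Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The design, tests, gene lists, naming rule and alternatives were chosen before the data were examined, apart from the exceptions given with the alternatives. Genes with at least 1 CPM in at least 2 of the 9 libraries were kept (18237) and scaled by TMM. An additive edgeR quasi-likelihood model had terms for acetaminophen (3 library pairs), exosomes (2), caffeine (2) and arsenic (3 libraries). The arsenic coefficient compares these libraries with the untreated level that the model fits from the libraries without arsenic. The model had 5 coefficients and 4 residual degrees of freedom. The common dispersion was 0.283 and the prior degrees of freedom 32.5. Acetaminophen by exosomes, acetaminophen by caffeine, arsenic at 15 µM and copper were each tested as 1 extra term, with 3 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and DESeq2 with the same terms was run beside edgeR. The SE given with a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. It is not a standard error estimated by the model.

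Between 2 libraries, ratios of TMM-scaled CPM were given with the exact conditional binomial 95% interval for 12 pairs. Genes were counted as apart when the ratio was at least 2 either way, with 0.5 prior counts, and the interval excluded 1. A gene with no counts in a library was set to 3 counts in that library for a bound on its ratio. For the acetaminophen response by background, genes apart in 1 of 3 pairs that share no library were followed in the other pairs by their median log2 ratio, signed by the selecting pair. The 95% intervals of these and other medians over genes come from order statistics and treat genes as independent. They do not cover variation between cultures.

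Gene lists (45, of which 44 had at least 3 tested members; 1045 of 1088 entries matched an identifier) were tested by camera with an inter-gene correlation of 0.01, with adjustment over lists and factors together, and again with the correlation estimated per list and with fry. For each library pair the list median was also placed among 10000 random lists matched on expression.

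Named genes followed a fixed rule. For each of the 4 factors they were called genes with a mean of at least 5 CPM and the same sign in every pair, up to 10 per direction by fold, filled up to 5 by p as values alone where fewer passed. For extra terms they were the 5 genes with the smallest p. Up to 4 members per list were taken by fold, and for each pair the 5 genes highest and 5 lowest by the interval bound nearest to 1, of which a part is named.

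Alternatives were DESeq2 size factors, no count filter, DESeq2, protein-coding genes alone, each library left out in turn, the 6 libraries without arsenic, arsenic dose as a number, the arsenic libraries with the control alone, a prior count of 5, and a selection at a log2 ratio of 2. After the values were seen, per-library trends with GC content and length were removed through offsets (natural splines with 5 degrees of freedom), and the acetaminophen and arsenic 5 µM libraries were left out together. The workflow was tested on simulated data of the same depths. Of 50 genes changed 8 times, 40 were recovered for acetaminophen, 22 for arsenic, 23 for caffeine, 24 for exosomes and 6 for the 15 µM term, and of 50 changed 64 times 50, 48, 49, 47 and 43, with 2 to 4 false calls each. A shifted list of 30 genes passed camera and 0 unshifted lists did. The simulated genes varied independently of each other and without GC or length trends. These false calls and list results therefore do not measure error rates in the real libraries. Pair intervals, simulated at the depths of the arsenic 15 µM and control libraries, held 96.9% of the true ratios. Among the 18237 genes, 207 without a change were counted as apart. These counts were drawn with counting error alone, as the intervals assume, so they do not measure error between cultures.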

Results

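Ribosomal RNA-depleted total RNA of the human hepatocellular carcinoma line HuH-7 was sequenced under 9 conditions with 1 library each: an untreated control, acetaminophen at 10 mM, serum exosomes, acetaminophen with exosomes, caffeine at 2 mM, acetaminophen with caffeine, arsenic at 5 µM, arsenic at 15 µM, and arsenic at 5 µM with copper at 5 µM. The libraries held between 658725 (acetaminophen with exosomes) and 8227906 (caffeine) counts on genes, with 951816 in the control, and 18237 genes were tested. No condition was replicated, so the tests take departures from additive effects as their spread. Counting intervals of ratios between 2 libraries cover counting error alone, and intervals of medians over genes treat genes as independent. Neither kind covers variation between cultures. The reads are PCR reads without molecular tags. Levels are given as TMM-scaled CPM.

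The libraries differed in their make-up. Small nucleolar RNA genes took 4.86% of the counts in the control, 11.5% in the acetaminophen library and 35.5% in the arsenic 5 µM library. In these last 2 libraries, log2 levels relative to the mean of all 9 fell with the GC content of the gene (Pearson's r -0.633 and -0.509), against 0.256 in the control. Such levels rose with GC content in acetaminophen with caffeine (r 0.381) and in arsenic 5 µM with copper (r 0.431). Correlation between libraries ranged from 0.585 (arsenic 5 µM and acetaminophen with caffeine) to 0.942 (exosomes and control). DESeq2 size factors in place of TMM shifted the log2 ratios of the 12 library pairs by -0.18 to 0.15, so a gene or list median closer to 0 than the shift of its pair has no settled direction.

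**Figure D1:**
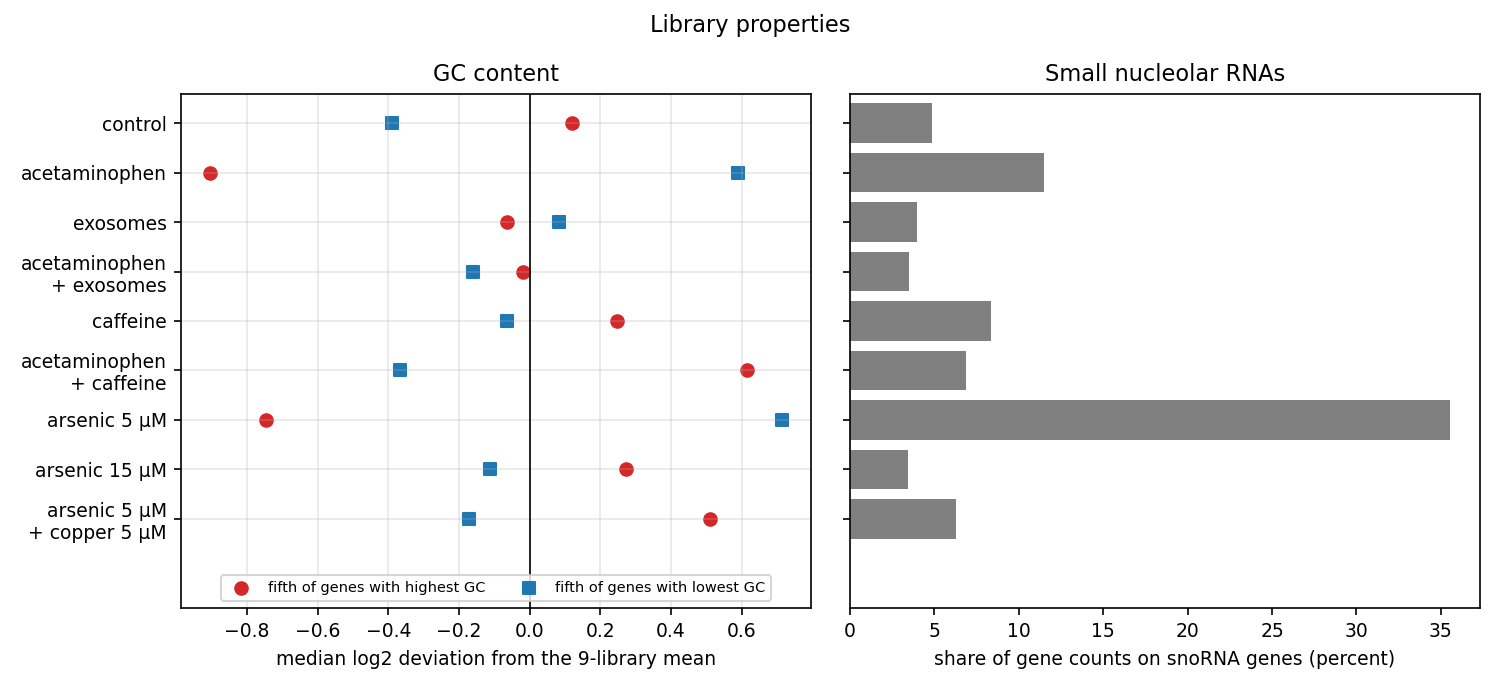
Median log2 deviation of the genes with the highest and lowest GC content from the mean of the 9 libraries (left, horizontal axis), and percent of gene counts on small nucleolar RNA genes (right, horizontal axis), per library. The acetaminophen and arsenic 5 µM libraries had small nucleolar RNA shares of 11.5% and 35.5%.

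Acetaminophen was compared on 3 backgrounds (no other treatment, exosomes, caffeine). The genes NR1H4, ARG1 and PLK1 had lower levels with it on each, although each missed the test over all genes. NR1H4, the bile acid receptor FXR, stood at 120, 100 and 72 CPM without the drug and at 18.2, 22.9 and 6.97 CPM with it. The urea cycle enzyme ARG1 was at 14.5, 8.06 and 27.8 CPM without and at 0.702, 1.27 and 0.377 CPM with it. These ARG1 levels with the drug lay under the 3-count floors of their libraries (2.11, 3.82 and 0.565 CPM). The mitotic kinase PLK1 was at 175, 171 and 68.3 CPM without and at 28.1, 26.7 and 40.5 CPM with it. Their edgeR adjusted p was 0.1, 0.055 and 0.32.

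In the additive edgeR model, 4 genes passed for acetaminophen. The membrane adaptor gene EFR3B rose (log2 fold change 4.02, SE 0.721, adjusted p 0.015; 0.965, 2.99 and 3.28 CPM without and 16.1, 26.7 and 89.9 CPM with the drug). MYH4, a myosin heavy chain (-5.42, SE 0.838, adjusted p 0.0028), the calcium pump gene ATP2B2 (-3.51, SE 0.602, adjusted p 0.01) and TM4SF4, a tetraspanin-like membrane protein (-4.39, SE 0.811, adjusted p 0.019), fell. With the drug, MYH4 (0, 1.27 and 0.565 CPM) lay at or under the 3-count floors of its libraries (2.11, 3.82 and 0.565 CPM). TM4SF4 (0.702, 1.27 and 1.88 CPM with the drug) lay under the first 2 of these floors. EFR3B in the control lay under the floor there, 2.89 CPM. The folds of these 3 genes are therefore imprecise. BAIAP3, GLIPR2, CRISPLD2 and the guidance factor SLIT2 were higher in all 3 pairs at adjusted p 0.055. At an unadjusted p under 0.05 there were 975 genes, and DESeq2 called 52. The count was 0 with any single library of the 6 without arsenic left out, and 179 without arsenic 5 µM.

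Of the 44 gene lists tested, 15 passed for acetaminophen by camera with its preset correlation of 0.01, 2 higher and 13 lower, and 0 passed with the correlation estimated for each list (smallest adjusted p 0.633). Here and for the other terms, members are counted as higher or lower by the sign of their additive coefficient, which single library pairs need not share. Of 19 bile acid and transporter genes, 15 were lower (camera adjusted p 2.28e-06, estimated-correlation adjusted p 0.633). Their pair medians were -1.08, -1.16 and -2.16 on the log2 scale. With genes absent from a library set to their 3-count bound, the exosome and caffeine medians were -0.295 and -1.94. All 36 secreted hepatocyte proteins had a negative coefficient (camera adjusted p 2.54e-06, estimated-correlation adjusted p 0.633; pair medians -0.72, -0.61 and -0.57), as did 15 of 18 urea cycle and amino acid genes (camera adjusted p 2.87e-05, estimated-correlation adjusted p 0.633). The ribosome assembly list was lower for 28 of 29 genes (camera adjusted p 2.42e-06, estimated-correlation adjusted p 0.633), with pair medians of -0.27 (13 of 29 higher), -0.84 and -0.97. The mitosis list was lower for 24 of 30 (camera adjusted p 0.00125, estimated-correlation adjusted p 0.808). The mitosis median was 0.13 in the pair without other treatment and -1.02 and -0.40 in the other pairs. Of 21 p53 targets 16 were higher (camera adjusted p 0.00498, estimated-correlation adjusted p 0.633). CDKN1A, an inhibitor of cyclin-dependent kinases, was at 9.65, 8.36 and 24.1 CPM without and 9.83, 36.9 and 106 CPM with the drug. Over all genes 0 members of these lists passed edgeR; adjusted over the list alone, 7 bile acid genes were lower and 1 higher, and 3 urea cycle and amino acid genes were lower.

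The 26 replication histone genes all had a negative acetaminophen coefficient (camera adjusted p 1.18e-15, estimated-correlation adjusted p 0.633), but the pairs were uneven. Of the 26, 0 were higher without other treatment, 4 with exosomes and 11 with caffeine as background. Pair medians were -3.33 without other treatment (-3.06 with absent genes at their bound), -1.15 with exosomes and -0.19 with caffeine. Over all genes 0 histone genes passed edgeR, and 4 were lower adjusted over the list alone. Ribosomal protein genes were lower for 70 of 77 (camera adjusted p 0.00158, estimated-correlation adjusted p 0.865), which came from the pair without other treatment (-2.06), since the other pairs had medians of 0.34 and 0.30. Both families have near-identical copies or pseudogenes, so the level of a single member is uncertain.

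**Figure D2:**
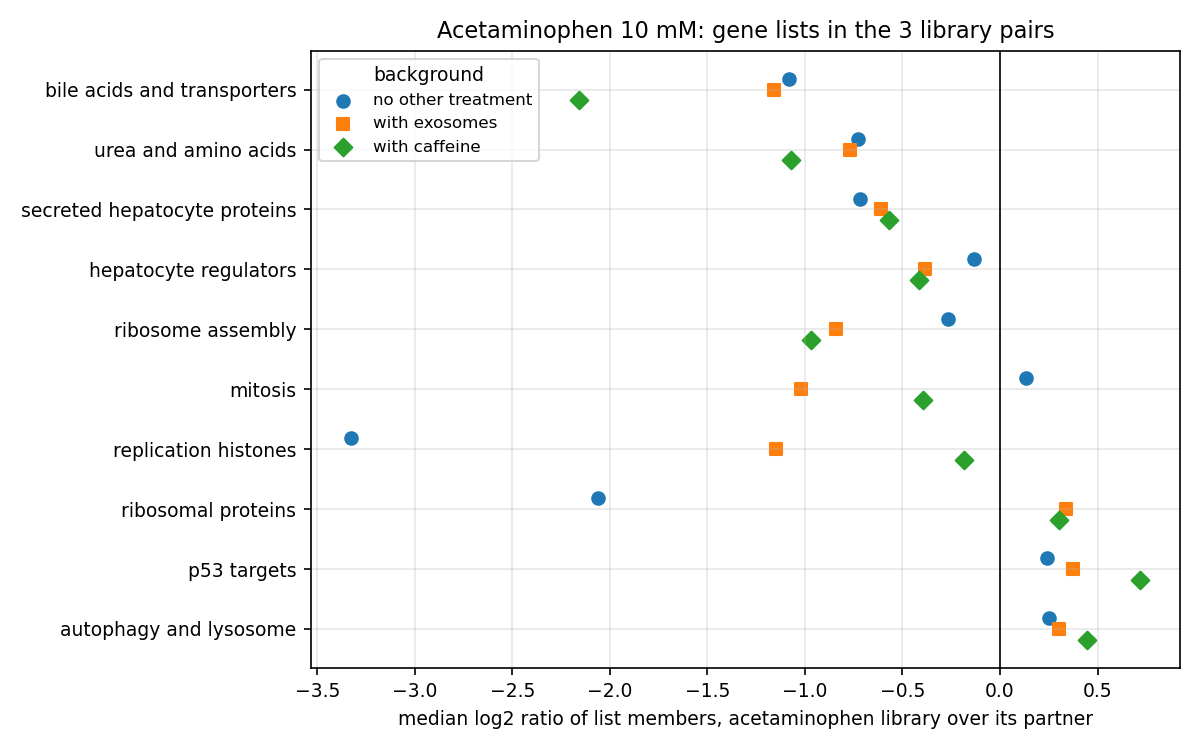
Median log2 ratio of list members (horizontal axis), acetaminophen library over its partner without the drug, for 10 gene lists (vertical axis) on the 3 backgrounds. Bile acid genes had medians of -1.08, -1.16 and -2.16, and replication histones -3.33, -1.15 and -0.19.

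Between libraries, 4598 genes lay at least 2 times apart with a counting interval excluding 1 for acetaminophen against the control (2387 higher, 2211 lower), 1918 for acetaminophen with exosomes against exosomes (939 higher, 979 lower), and 4676 for acetaminophen with caffeine against caffeine (2290 higher, 2386 lower). Against the control, the chaperone gene HSPB1 was at 2.11 against 170 CPM (ratio 0.0124, counting interval 0.00253 to 0.0368), and the small nucleolar RNA SNORD7 was 85.6 times higher. With caffeine as background, the sodium pump subunit gene ATP1B2 was at 52.2 against 0.117 CPM, the neurotrophin receptor gene NGFR at 146 against 1.87 CPM, and CYP1A1, the inducible cytochrome of polycyclic hydrocarbon metabolism, at 7.92 against 236 CPM. With exosomes as background, TAGLN, an actin-binding protein gene, was at 3.82 against 60 CPM. All 36 possible pairs of the 9 libraries gave 937 to 7637 such genes, with a median of 5090.

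As counted, the response on the exosome background resembled the one on the caffeine background more than the one without other treatment. Genes apart in the exosome pair had a median signed log2 ratio of 0.92 in the caffeine pair (95% interval 0.851 to 0.98; 80.7% with the same sign), and genes apart in the caffeine pair one of 0.62 in the exosome pair (0.587 to 0.645; 74.0%). Genes apart in the pair without other treatment had medians of 0.00 (-0.025 to 0.025; 50% with the same sign) and -0.03 (-0.066 to -0.002; 48.3%) in the exosome and caffeine pairs. Across 11148 genes, Pearson's r of the log2 ratios was 0.515 between the exosome and caffeine pairs, 0.032 between the exosome pair and the pair without other treatment, and 0.045 between the caffeine pair and the latter. With GC and length trends removed (10985 genes), r was 0.531, 0.15 and 0.214. The 741 genes apart in the same direction in the exosome and caffeine pairs then had a median signed log2 ratio of 0.664 in the pair without other treatment, 74.8% with the same sign. No library is shared by these pairs.

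The edgeR interaction test of acetaminophen with exosomes called 0 genes (87 at an unadjusted p under 0.05, 0 by DESeq2), and that with caffeine called 0 genes (198 at an unadjusted p under 0.05, 0 by DESeq2). Each of these terms rests on 1 library with 3 residual degrees of freedom. The smallest p for exosomes belonged to RNU5A-2P, GCKR, RNU5E-4P, RPS19P1 and OVOL1, and for caffeine to FSCN1, LFNG, CORO6, CYP1A1 and B3GNT5, all at an edgeR adjusted p of 1. FSCN1, which bundles actin, was at 10.6 CPM with caffeine and 247 CPM with caffeine and acetaminophen, against 106 CPM in the control and 37.2 CPM with acetaminophen.

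Exosomes left the HuH-7 profile close to the control: the 2 libraries had 937 genes apart, the fewest of all 36 pairs, with 681 higher and 256 lower. The scaffold protein gene AHNAK was at 739 CPM with exosomes and 236 CPM in the control, and EEA1, an early endosome tethering gene, at 53.4 and 8.68 CPM. Both genes have long transcripts, and the control library held less of long genes (Pearson's r of log2 deviation with transcript length -0.437). The exosome term had 0 genes by edgeR (113 at an unadjusted p under 0.05, 0 by DESeq2). Adding exosomes to acetaminophen put 3502 genes apart (1855 higher, 1647 lower), among them RPS19 at 1400 against 26 CPM and SNORD7 at 22.9 against 2810 CPM. The control had 729 and 32.8 CPM of these, so the acetaminophen library was the one far from it.

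For the exosome term 2 of 44 lists passed camera. Ribosomal protein genes had a positive coefficient for 68 of 77 (camera adjusted p 5.06e-07, estimated-correlation adjusted p 0.808), yet their median was -0.50 for exosomes against the control and 1.93 for acetaminophen with exosomes against acetaminophen, so the term had no common direction. Endoplasmic reticulum chaperone genes were lower for 14 of 21 (camera adjusted p 0.0468, estimated-correlation adjusted p 0.757; pair medians -0.08 and -0.51). The genes with the smallest p were RNA5-8SP2, RNA5-8SP4, RNU1-146P, CHP1P2 and RPL6P27 (higher) and SNORD83A, SNORD9, SNORA15, SNORA11F and SNORD8 (lower), all at an edgeR adjusted p of 1; several are pseudogene copies whose reads are hard to place.

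NQO1, the quinone reductase gene, was lower in both caffeine libraries, at 44.7 against 600 CPM without acetaminophen and 11.9 against 682 CPM with it. AGR2, a secretory-pathway disulfide isomerase, went from 115 to 1.17 CPM and from 10.5 to 0.942 CPM. The coagulation factor gene F12 went from 0.965 to 66.7 CPM and from 1.4 to 24.1 CPM, and LRP2, the endocytic receptor megalin, from 2.89 to 128 CPM and from 9.12 to 87.5 CPM. The lactase gene LCT was at least 26.1 times higher with caffeine than in the control, where it had no counts (75.5 CPM with caffeine; 0.702 CPM with acetaminophen and 10.7 CPM with both).

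By edgeR 15 genes passed for caffeine, 4 higher and 11 lower (1334 at an unadjusted p under 0.05, 56 by DESeq2). The higher genes were LCT (adjusted p 0.038), F12 (log2 fold change 4.96, SE 1.02, adjusted p 0.031), the lipid transporter gene ABCA7 (4.58, SE 0.949, adjusted p 0.034) and LRP2 (4.19, SE 0.819, adjusted p 0.023). With DESeq2 size factors the calls were 0 higher and 7 lower, and these 4 genes had adjusted p of 0.11, 0.074, 0.1 and 0.05. The count was 0 without the control or without acetaminophen with exosomes, and 221 without arsenic 5 µM. Among the lower genes were the arginine methyltransferase gene PRMT6 (-6.92, SE 1.25, adjusted p 0.012), AGR2 (-5.36, SE 0.942, adjusted p 0.011), the calcium channel gene CACNA1H (-4.87, SE 0.808, adjusted p 0.0072), NQO1 (-4.77, SE 0.912, adjusted p 0.022), RAPGEF4, a cAMP-activated exchange factor (-4.34, SE 0.838, adjusted p 0.022), and RNU2-25P (-4.17, SE 0.796, adjusted p 0.022), a U2 pseudogene whose reads are hard to place. Caffeine put 3740 genes apart against the control (2190 higher, 1550 lower) and 6167 when added to acetaminophen (3461 higher, 2706 lower).

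Of the lists, 14 passed camera for caffeine, 6 higher and 8 lower, and 0 with estimated correlation (smallest adjusted p 0.633). All 8 gluconeogenesis genes were higher (camera adjusted p 0.000949, estimated-correlation adjusted p 0.633). The list median was 1.83 against the control and 1.89 when caffeine was added to acetaminophen. With absent genes at their bound these were 1.36 and 0.663. In each pair 3 of the 8 were counted as apart. PCK1, the cytosolic gluconeogenic enzyme, was at 37.1 CPM with caffeine and had no counts in the control. All 9 metallothionein genes had a negative caffeine coefficient (camera adjusted p 3.62e-05, estimated-correlation adjusted p 0.757), with MT1E at 0.702 against 39.6 CPM in the control, and the copies of this family are near-identical. Their median was -3.36 against the control but -0.08 when caffeine was added to acetaminophen, with 4 genes higher and 5 lower. Ribosome assembly genes were lower for 26 of 29 (camera adjusted p 2.63e-05, estimated-correlation adjusted p 0.633), heat shock genes for 20 of 24 (camera adjusted p 0.000515, estimated-correlation adjusted p 0.808) and proteasome genes for 29 of 33 (camera adjusted p 0.000165, estimated-correlation adjusted p 0.74). Secreted hepatocyte proteins were higher for 25 of 36 (camera adjusted p 0.0183, estimated-correlation adjusted p 0.761), with APOC3, an apolipoprotein gene, at 232 and 167 against 38.6 and 13.3 CPM. This list missed the threshold without the acetaminophen and arsenic 5 µM libraries (camera adjusted p 0.173). Biliary and progenitor markers were lower for 7 of 9 with caffeine (camera adjusted p 0.00507, estimated-correlation adjusted p 0.633), 8 of 9 with acetaminophen (0.0103 and 0.633) and 7 of 9 with arsenic (0.0427 and 0.633). Over all genes 0 members of these lists passed edgeR; adjusted over the list alone, 2 gluconeogenesis and 3 secreted protein genes were higher, and 3 metallothioneins and 2 biliary and progenitor markers lower with caffeine.

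Single genes of the stress response rose with arsenic. HMOX1, the heme oxygenase gene, went from 31.8 CPM in the control to 1080 at 5 µM, 5100 at 15 µM and 3330 CPM at 5 µM with copper. The heat shock gene HSPA6 had no counts in the control and reached 12.3, 4760 and 268 CPM, at least 1640 times higher at 15 µM. GDF15, a stress cytokine gene, went from 7.72 to 33.6, 349 and 105 CPM, and SLC7A11, the cystine transporter gene, from 20.3 to 465, 526 and 178 CPM. Fibrinogen chain FGA stood at 509 CPM in the control and at 93.1, 17.2 and 164 CPM with arsenic, with an edgeR adjusted p of 0.13.

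By edgeR 90 genes passed for arsenic, 62 higher and 28 lower (1671 at an unadjusted p under 0.05, 175 by DESeq2). The count was 24 with DESeq2 size factors, 12 for protein-coding genes and 0 with the arsenic libraries and the control alone (722 at an unadjusted p under 0.05). With single libraries left out it ranged from 0 (without the control or acetaminophen with exosomes) to 780 (without arsenic 5 µM). Of the genes named by rule for arsenic, RNVU1-6 alone passed in every alternative that tested it with all its libraries. It was not tested among protein-coding genes or in the arsenic libraries with the control alone. HMOX1 (log2 fold change 7.14, SE 1.12, adjusted p 0.0021) rose. Genes without counts in the control were called higher too: HSPA6 (adjusted p 0.0021), PREX1, a Rac exchange factor (adjusted p 0.014), the cytokine gene IL11 (adjusted p 0.015; at least 174 times higher at 15 µM), DIO3 (adjusted p 0.03), CATSPERG (adjusted p 0.028), PLA1A (adjusted p 0.014), FOSB (adjusted p 0.044) and the pseudogene RPL13AP11 (adjusted p 0.013). The calls of PREX1, DIO3, CATSPERG and FOSB were carried by the 15 µM library (92.5, 80.3, 22.6 and 95.4 CPM, against 2.55, 1.28, 2.13 and 0.425 CPM at 5 µM), and without it their adjusted p was 0.12, 0.52, 0.093 and 0.18. CATSPERG and FOSB were also at 15.1 and 9.05 CPM in acetaminophen with caffeine. The mucin gene MUC19 (-5.14, SE 1.08, adjusted p 0.016), the trefoil factor gene TFF2 (-4.40, SE 0.898, adjusted p 0.014), the elastase inhibitor gene PI3 (-4.14, SE 0.896, adjusted p 0.02), AGMO (-4.15, SE 0.997, adjusted p 0.043) and SYP (no counts in the arsenic libraries; adjusted p 0.024) fell. So did RNVU1-6, RNU6-14P, RNU2-44P, RN7SL521P and RPL13AP22 (adjusted p 0.011, 0.014, 0.014, 0.02 and 0.0098), copies of small RNA or ribosomal protein genes whose reads are hard to place; without the control library, RNU6-14P and RN7SL521P turned to log2 fold changes of 0.687 and 1.88. Low levels were not limited to arsenic: against 130, 35.7 and 43.4 CPM in the control, RN7SL521P, RNU6-14P and RPL13AP22 were at 2.11, 0.702 and 11.2 CPM with acetaminophen and at 5.03, 3.28 and 0.702 CPM with caffeine.

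For arsenic 19 lists passed camera, 10 higher and 9 lower, and 0 with estimated correlation (smallest adjusted p 0.235). Endoplasmic reticulum chaperone genes had a negative coefficient for 17 of 21 (camera adjusted p 0.0776, estimated-correlation adjusted p 0.761). Integrated stress response genes were higher for 26 of 28 (camera adjusted p 4.78e-17, estimated-correlation adjusted p 0.633), with 4 passing over all genes and 22 higher and 1 lower adjusted over the list alone. Of 27 NRF2 targets 25 were higher (camera adjusted p 2.35e-13, estimated-correlation adjusted p 0.235), 3 of them over all genes and 10 adjusted over the list alone. List medians were 1.08, 1.43 and 1.83 at 5 µM, 15 µM and 5 µM with copper (1.75 for the last with absent genes at their bound). All 9 metallothionein genes had a positive arsenic coefficient (camera adjusted p 8.24e-08, estimated-correlation adjusted p 0.633), 2 passing over all genes and 7 over the list alone, and 7, 8 and 9 of them were above the control at 5 µM, 15 µM and 5 µM with copper. Of 24 heat shock genes 23 were higher (camera adjusted p 3.37e-06, estimated-correlation adjusted p 0.761), 5 over all genes and 8 over the list alone. Nuclear genes of oxidative phosphorylation were lower for 49 of 51 (camera adjusted p 1.47e-06, estimated-correlation adjusted p 0.757), and secreted hepatocyte proteins for 31 of 36 (camera adjusted p 1.47e-06, estimated-correlation adjusted p 0.633). The same held for replication histones for 24 of 26 (camera adjusted p 2.54e-06, estimated-correlation adjusted p 0.791) and DNA replication genes for 23 of 27 (camera adjusted p 2.63e-05, estimated-correlation adjusted p 0.757). The oxidative phosphorylation and histone lists were not low with arsenic alone. Against the control, their medians were -1.07 and -3.33 with acetaminophen, -0.384 and -0.675 with exosomes, and -0.818 and -1.6 with caffeine. The other lists named as lower were mixed there. Secreted proteins had medians of -0.717 with acetaminophen, -0.0542 with exosomes and 0.452 with caffeine. DNA replication genes had 0.314, -0.0454 and -0.713. Of the lower lists, the secreted proteins had 1 gene past the threshold over all genes and 2 adjusted over the list alone, and the histones 0 and 3. Against the control, 5722 genes were apart at 5 µM (3017 higher), 5632 at 15 µM (3037 higher) and 2984 at 5 µM with copper (1708 higher).

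The 15 µM library stood out for heat shock and immediate early genes. FOS, an early transcription factor gene, was at 2.13 CPM at 5 µM, 17.4 CPM with copper and 372 CPM at 15 µM. The chaperone genes DNAJB1 and CRYAB went from 70.6 to 4350 and from 1.7 to 305 CPM between 5 and 15 µM. HSPA1A was 183 times higher at 15 than at 5 µM, but its near-identical copy HSPA1B was at 439 CPM at 5 µM, so the split of reads between the copies is uncertain. Of 27 immediate early genes 25 were higher for arsenic (camera adjusted p 8.32e-06, estimated-correlation adjusted p 0.808). Their medians against the control were -0.34 at 5 µM, 1.16 at 5 µM with copper and 3.25 at 15 µM (3.13 for the last with absent genes at their bound).

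The edgeR term for 15 µM against the other arsenic libraries had 198 genes, 145 higher and 53 lower (1846 at an unadjusted p under 0.05, 96 by DESeq2). The smallest p belonged to DNAH17 (log2 fold change 5.22, SE 0.814, adjusted p 1.3e-06), FOS (5.23, SE 0.816, adjusted p 1.3e-06), RASGEF1B (5.12, SE 0.858, adjusted p 1.4e-05), IL11 (4.69, SE 0.794, adjusted p 1.5e-05) and WNT11 (5.43, SE 0.924, adjusted p 1.5e-05). This term rests on 1 library of 15 µM, and its count ranged from 17 (without arsenic 5 µM) to 775 (without the copper library) with single libraries left out. Between the 15 and 5 µM libraries 6768 genes were apart (3582 higher, 3186 lower), among them SNORD15B at 131 against 21200 CPM. The control had 261 CPM of SNORD15B, so the 5 µM library was the one far from it.

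**Figure D3:**
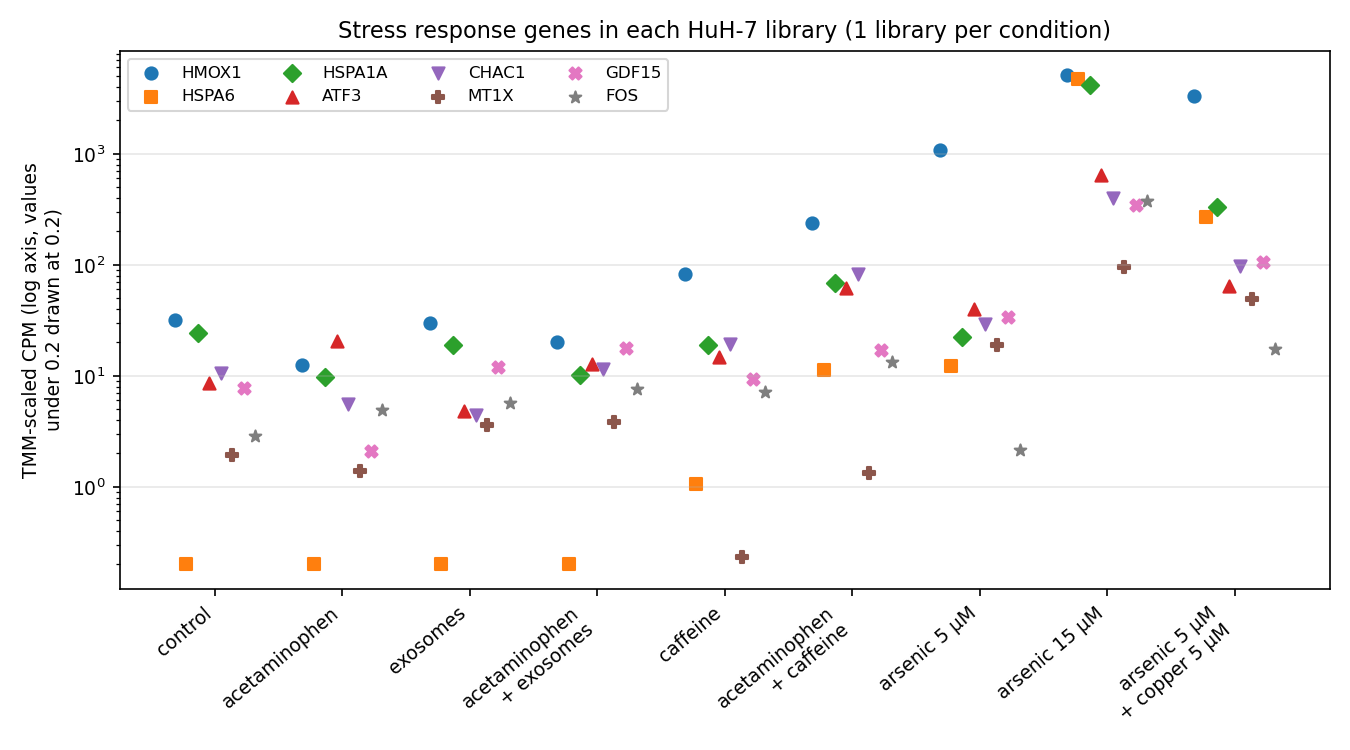
TMM-scaled CPM (vertical log axis) of 8 stress genes in each of the 9 libraries (horizontal axis). HMOX1 was at 31.8 CPM in the control and at 1080, 5100 and 3330 CPM in the arsenic libraries, and GDF15 at 7.72, 33.6, 349 and 105 CPM.

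With copper, the HMOX1 level at 5 µM arsenic was 3330 against 1080 CPM without it, and HSPA6 was 21.7 times higher (counting interval 15 to 32.7). The biliverdin reductase gene BLVRB was at 138 against 7.23 CPM, and JUNB, an early transcription factor gene, at 28.2 against 0.425 CPM. The control had 24.1 and 10.6 CPM of BLVRB and JUNB, so for both the 5 µM library was below the control and the copper library above it. The GC trends of the 2 libraries were opposite (r 0.431 with copper, -0.509 without). Between these libraries 5517 genes were apart (3021 higher, 2496 lower). The edgeR copper term had 0 genes (428 at an unadjusted p under 0.05, 0 by DESeq2); the smallest p belonged to MIR3609, RN7SL679P, RSAD1, SNORD94 and PDE7B-AS1, all at an adjusted p of 1. MIR3609 was at 933 CPM at 5 µM, 9.64 CPM with copper, 3.23 CPM at 15 µM and 8.68 CPM in the control, so the 5 µM library was the one apart for this gene. No library had copper alone. The copper term rests on 1 library, and its count rose above 0 with arsenic 5 µM or arsenic 15 µM left out.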

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

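The share of reads that HTSeq set aside as ambiguous between genes differed between libraries. It was 3.36% in the control, 9.25% in the acetaminophen library, 5.74% in the caffeine library and 10.2% in the arsenic 5 µM library, with counting intervals of 3.34% to 3.38% in the control and 9.21% to 9.29% in the acetaminophen library. In the same 4 libraries small nucleolar RNA genes took 4.86%, 11.5%, 8.35% and 35.5% of the counts on genes. The ambiguous reads name no gene and were not analysed here.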

How the results depend on the processing

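The removal of GC and length trends and the joint omission of the acetaminophen and arsenic 5 µM libraries were chosen only after the values were seen; all other alternatives were planned. The number of acetaminophen genes (4) was 46 without a count filter, 52 by DESeq2, 249 in the 6 libraries without arsenic, 24 with GC and length trends removed and 58 without the acetaminophen and arsenic 5 µM libraries; the same 4 genes were among those called in each. It ranged from 0 to 179 with single libraries left out: 0 without any of the 6 libraries without arsenic, 179 without arsenic 5 µM, 124 without arsenic 15 µM and 14 without the copper library. The arsenic count (90) was 24 with DESeq2 size factors, 269 without a filter, 175 by DESeq2, 12 for protein-coding genes, 562 with dose as a number, 38 with trends removed, and 0 with the arsenic libraries and the control alone (edgeR, 722 at an unadjusted p under 0.05). With single libraries left out it ranged from 0 to 780: 0 without the control or acetaminophen with exosomes, 13 without acetaminophen, 140 without caffeine, 141 without acetaminophen with caffeine, 163 without the copper library and 780 without arsenic 5 µM. Without the control, the arsenic log2 fold changes of RNU6-14P and RN7SL521P reversed to 0.687 and 1.88; with each single library left out they ranged from -5.68 (without acetaminophen) to 0.687 and from -5.76 (without arsenic 15 µM) to 1.88.

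The caffeine count (15) was 7 with DESeq2 size factors (0 higher and 7 lower, against 4 and 11), 49 without a filter, 56 by DESeq2, 7 for protein-coding genes, 292 in the 6 libraries without arsenic and 72 without the acetaminophen and arsenic 5 µM libraries. With single libraries left out it ranged from 0 to 221: 0 without the control or acetaminophen with exosomes, 4 without acetaminophen or exosomes, 2 without caffeine, 6 without acetaminophen with caffeine, 153 without arsenic 15 µM and 221 without arsenic 5 µM. The exosome count of 0 became 3 in the 6 libraries without arsenic, and ranged from 0 to 3 with single libraries left out (3 without arsenic 5 µM, 1 without arsenic 15 µM). The 15 µM count (198) was 96 by DESeq2, 87 for protein-coding genes, 565 with trends removed and 1054 without the acetaminophen and arsenic 5 µM libraries. It ranged from 17 (without arsenic 5 µM) to 775 (without the copper library), with 319 without the control, 301 without acetaminophen, 64 without exosomes, 74 without acetaminophen with exosomes, 77 without caffeine and 80 without acetaminophen with caffeine. The copper count of 0 ranged to 52 (without arsenic 15 µM) and was 17 without arsenic 5 µM; without arsenic 5 µM the copper and 15 µM terms are the same comparison, hence the 1054 genes for copper without both libraries. Both interaction counts stayed at 0 by edgeR and DESeq2 in every alternative run.

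For the gene lists, 0 passed with estimated correlation and 0 by fry for acetaminophen, exosomes, caffeine and arsenic alike (15, 2, 14 and 19 by camera with the preset). Without the acetaminophen and arsenic 5 µM libraries 6 lists passed for exosomes, and ribosomal protein genes turned higher for acetaminophen (camera adjusted p 0.000105) and lower for exosomes (1e-13). In all 3 of the preset, trends-removed and reduced settings, 10 lists passed for acetaminophen, 0 for exosomes, 9 for caffeine and 15 for arsenic. The acetaminophen response of genes selected without other treatment was 0.028 on the exosome background with DESeq2 size factors, and 0.022 on the caffeine background with selection at a log2 ratio of 2, a reversed sign. With that selection the exosome to caffeine median was 1.269, caffeine to exosomes 0.945 and caffeine to no other treatment 0.307. All 36 alternatives of the pair counts stayed within 1.5 times. Of 40 named calls 17 passed in every alternative that tested the gene with all libraries. These were 4 acetaminophen, 7 caffeine and 5 dose calls and 1 arsenic call (RNVU1-6). RNVU1-6 and the caffeine call RNU2-25P were not tested among protein-coding genes. RNVU1-6 was also not tested in the arsenic libraries with the control alone, where 0 genes passed. HMOX1 missed the threshold with dose as a number (adjusted p 0.055) and with the arsenic libraries and the control alone (0.6), and HSPA6 with the latter (0.53). The cause of these differences was not tested. The labels name no pairs of cultures beyond the shared background, so pairing rests on the background terms of the model alone.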

Other observations

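The comparison of genes shared by the acetaminophen pairs and the test of a series shared with the arsenic libraries were chosen only after the values were seen. On the exosome and caffeine backgrounds, which share no library, acetaminophen put 741 genes apart in the same direction (337 higher, 404 lower) and 36 in opposite directions, where independent lists would share 79.5 higher and 130.6 lower. Among the higher genes were HES6, a repressor of the Notch pathway, from 7.17 to 54.7 and from 10.6 to 185 CPM, and SERTAD1, a cell cycle regulator gene, from 2.09 to 21.6 and from 4.33 to 68.4 CPM. Among the lower were the steroid dehydrogenase gene HSD17B2, from 17.3 to 1.27 and from 64.2 to 5.65 CPM, the alcohol dehydrogenase gene ADH6, from 12.2 to 1.27 and from 20.2 to 1.88 CPM, and KYNU, an enzyme of tryptophan breakdown, from 7.76 CPM to no counts and from 2.57 to 0.188 CPM. In acetaminophen with exosomes all of these lower genes lay under the 3-count floor of 3.82 CPM. KYNU in acetaminophen with caffeine also lay under the floor there, 0.565 CPM.

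The changes of the acetaminophen library against the control were hardly shared by the other acetaminophen pairs (r 0.026 and 0.044 across 10985 genes, against 0.518 between the other pairs). Low depth is argued against, since r between the exosome and caffeine pairs was 0.404 with all 6 libraries thinned to 658725 counts. Whether this was a mislabelled library of untreated cells is not settled. The 741 shared genes had a median signed log2 ratio of 0.664 in this library with GC and length trends removed (95% interval over genes 0.561 to 0.759), and 0.318 as counted. Untreated cells were predicted to give a median near 0. The same median was not taken for a library without the drug against the control. A difference between cultures in this direction therefore cannot be told apart from the drug. GC content and length remain a candidate explanation for part of the difference, because removing the trends raised the mean r with the other pairs to 0.182, between the bounds set for either answer. A preparation difference that the trends do not capture, or a culture that responded otherwise, also stays open, untested.

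Of the 11 genes called lower for caffeine, the 7 that met the naming rule (a mean of at least 5 CPM and lower in both pairs; among them PRMT6, AGR2, CACNA1H, NQO1, RAPGEF4 and RNU2-25P) may reflect caffeine or a difference between cultures. Loss of chromosome segments is argued against for these genes as a set, because the median over genes of the log2 ratio of the nearest expressed neighbours was -0.104 (70 neighbours with a median of -0.094, interval -0.404 to 0.197). By gene, the neighbour medians ranged from -0.68 for RAPGEF4 to 0.39 for CACNA1H, so the argument is weaker for RAPGEF4. Loss of single genes stays open. A series shared with the arsenic libraries stays open: the median log2 ratio of the 7 genes in the arsenic libraries against the 4 others was -0.874, with an interval of -3.50 to 2.11. NQO1 was at 858, 488 and 1110 CPM and CACNA1H at 188, 120 and 121 CPM in the arsenic libraries, whereas RAPGEF4 was at 4.25, 15.4 and 3.71 CPM.

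Across 11148 genes, 29 lay at least 2 times apart between every one of the 5 caffeine or arsenic libraries and every one of the other 4 (15 higher and 14 lower in the 4), with 0.5 CPM added to each level. Among them were HMOX1, HSPA6, MUC19, RPL13AP22 and RNU2-44P, which were also called for arsenic, and RNU2-25P, called for caffeine. HSPA6 had no counts in the 4 and 1.05 CPM with caffeine, which is under the 3-count floor of the control (2.89 CPM). HMOX1 was at 81.8 and 239 CPM in the caffeine libraries and at 12.6 to 31.8 CPM in the 4. Of the 126 splits of the libraries into 4 and 5, this was the 1 with the most, the highest other having 19 and the median 0. A library or culture series that divides the libraries in this way is a candidate explanation, and cannot be told apart from effects common to caffeine and arsenic, since the only control is among the 4. Caffeine and arsenic contrasts therefore carry this possible series difference in full, and acetaminophen contrasts within a background do not.

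The real choices of treated libraries were counted together with others. Of 83 choices of 3 libraries as treated in the acetaminophen term, 26 gave at least the 4 genes of the real choice, the real choice and its mirror (control, exosomes and caffeine, the same contrast with its sign turned) included, and the highest other gave 1278 (control, arsenic 15 µM and arsenic with copper), so chance is not excluded. For arsenic, 14 of 83 choices gave at least the real 90, again with the real choice and an equivalent of it (control, exosomes and caffeine) included, and the highest other gave 1058, so chance is not excluded there either. In both terms some of the other choices are also equivalent to each other, so these numbers are not shares of distinct choices. Some choices gave several times the real count. A structure of the samples that the additive terms do not describe is a possible reason, which was not tested.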
